A study of Homo sapiens with 53 samples.

How the data were processed

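Total RNA from 53 snap-frozen renal tumours of childhood was measured on Affymetrix oligonucleotide arrays, 1 array per tumour. Tumours were grouped by the type in their labels: 10 rhabdoid tumours (RT), 16 clear cell sarcomas of kidney (CCSK), 12 cellular mesoblastic nephromas (CMN) and 15 Wilms tumours (WT). Per the labels' protocols, RNA was extracted with Trizol, treated with DNase and purified on columns. Per the design text, tumours with too few viable tumour cells and arrays past quality limits had been left out. Tumours were taken as separate samples, as numbered in the labels, and p-values measure the spread between these tumours. Where a comparison pools types, this spread includes the differences between the pooled types.

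The expression table as deposited holds 22283 probesets on a natural log scale. Per the design text, the authors had turned the array images into expression values and normalized them across all arrays with software based on a positional-dependent-nearest-neighbor model. The base of the log is not stated in the sources used here and was settled from the values, because the fold changes deposited by the authors equal ratios of group means of the exponentiated values. The arrays' number limits the precision of each value, and their detection calls were not used here. Values were converted to log2, so a log2 change is a difference of mean log values.

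The authors also deposited 3 tables of results. Per the file headers, the first gives a fold ratio, a p-value and a q-value for 2921 probesets in RT against all other tumours. All 2921 folds were matched within 1% by the mean of the exponentiated values in RT over the equally weighted mean of the other 3 type means. All 2921 p-values were matched within 0.01 log10 units by a t-test with unequal variances. The design text gives a p-value limit of 0.005 for this table, whereas the deposited entries correspond to p under 0.001, which 2923 probesets met here, 2921 of them in the table. How the authors made the q-values is not given in the sources used here. The second table holds ratios and p-values of 426 probesets that, per the design text, passed p under 0.001 in all 4 comparisons of RT, and the third, per the design text, holds Bonferroni-corrected p-values of biological processes from the PANTHER tool.

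Gene names came only from the authors' deposited tables, because no annotation of the whole array was used here. Of the 2921 listed probesets, 2761 had 1 gene symbol, 79 several and 81 none, and probesets outside the tables stayed unnamed. Symbols were brought up to date with RefSeq names of assembly GRCh38.p14: 2325 were current, 377 were updated and 56 kept the file's symbol. Of 11 symbols turned into dates by a spreadsheet, 6 could be named. The names cover 2201 genes, for 4 of which named probesets changed in opposite directions in RT against non-RT. Because names exist only where the authors found a difference between RT and the other tumours, the share of a gene list that changed says little about its unnamed members. Gene coordinates were not used apart from the chromosome arm in the authors' tables. Leaving out 3 Y-linked probesets left 22280 probesets for testing, which include 68 array controls.

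Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no covariate), and probesets with a Benjamini-Hochberg adjusted p under 0.01 were called. RT was compared with all 43 other tumours and with each type in a fit of those 2 types alone, and each other type was compared with the remaining tumours. The intersection took probesets with an unadjusted p under 0.001 in all 4 RT comparisons with the same direction. Errors of log2 changes are standard errors from limma, and errors of levels are SDs over tumours. RNA quality was compared with 2-sided permutation tests.

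The comparisons, 38 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Lists were tested with camera from limma on 1 probeset per gene, the one with the highest mean, with a preset correlation of 0.01. The limit was an adjusted p under 0.05 over the lists of a comparison. Only the 2201 named genes entered, so each list was set against other genes selected by the authors, not against all genes on the array. Of the 38 lists 21 had at least 3 named genes and were tested, 10 had fewer and 7 had none. With an estimated correlation no list call held in any of the 4 comparisons. Genes were named by rule: *SMARCB1*, the 10 largest increases and 10 largest decreases in RT against non-RT, 5 and 5 against each type, 10 and 10 of the intersection by their smallest change, up to 4 members of a list, and 5 and 3 for each other type, each by the called probeset with the largest change. A gene that the rule names, a member of the simple epithelium list and a decrease in CMN against the rest, is not reported by name, because its probesets may match another copy of the gene.

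Alternatives were pooled and unequal-variance t-tests, eBayes with trend and robust settings, median centring, quantile normalization, leaving out the dimmest 30% of probesets, array weights, a fit of all 4 types, an RNA quality covariate, the tumour number as a block, leaving out each RT tumour, other probesets per gene, other thresholds, and dividing the RT among the comparisons. Leaving out CCSK 9, leaving out CMN 11, CMN 12 and CMN 13, drawing 10 non-RT tumours and an endothelial covariate were added after the data were seen.

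The procedure was tested on simulated data of 22280 probesets with 200 planted changes in 5 runs. In RT against non-RT it recovered 89% of log2 changes of 0.5, 98.5% of 1 and 100% of 2, with 1.44% false calls. Recovery of log2 changes of 0.5 was 77.9% in RT against CCSK, 77% against CMN, 78.8% against WT and 77.9% in the intersection. Apart from the planted changes, the simulated types shared the same mean and SD of each probeset, with independent normal noise. The real types differ in mean and spread and their genes are correlated, so these rates hold for the simulated setting only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 handled names, author tables and figures.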

Results

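Expression was measured in 53 frozen renal tumours of childhood, each on 1 oligonucleotide array. The rhabdoid tumours (RT, n = 10) were set against clear cell sarcoma of the kidney (CCSK, n = 16), cellular mesoblastic nephroma (CMN, n = 12) and Wilms tumour (WT, n = 15), and these last 3 types together form the 43 non-RT tumours. Rhabdoid tumour is an aggressive cancer of early childhood defined by inactivation of *SMARCB1*, which encodes a core subunit of the SWI/SNF chromatin remodelling complex. CCSK and CMN are mesenchymal tumours, and WT is an embryonal tumour that resembles the developing nephron. Each array held one tumour and no replicate arrays were labelled, so the errors given here are spreads between tumours, and the number of tumours limits their precision. The fit of RT against non-RT has no term for type, so its errors also hold the differences among CCSK, CMN and WT.

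The 4 tumour types formed separate groups on the main axes of variation. CCSK separated from the others along principal component 1, with a mean of 33.0 ± 4.68 (SD, n = 16) against -21.2 ± 2.99 (n = 10) in RT. RT separated along component 3, where its tumours lay between 16.4 and 37.1 and the highest tumour of any other type, a CCSK, lay at 8.36. The median log2 value of an array ranged from 9.16 to 9.28. RNA quality was read from the log2 difference between 3′ and 5′ control probesets of *GAPDH* and beta-actin, averaged over both genes. It was 1.41 ± 0.43 (SD, n = 10) in RT, 1.82 ± 0.57 (n = 16) in CCSK, 1.45 ± 0.99 (n = 12) in CMN and 1.55 ± 0.49 (n = 15) in WT, and the difference between RT and non-RT of -0.22 did not pass a 2-sided permutation test (p = 0.354). The arrays CMN 11, CMN 12 and CMN 13 had beta-actin differences of 3.18, 4.00 and 3.67. Those of CCSK 18 and CCSK 16 were similar, 3.84 and 3.00. CCSK 9 had the narrowest spread of values (SD 0.80).

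**Figure D1:**
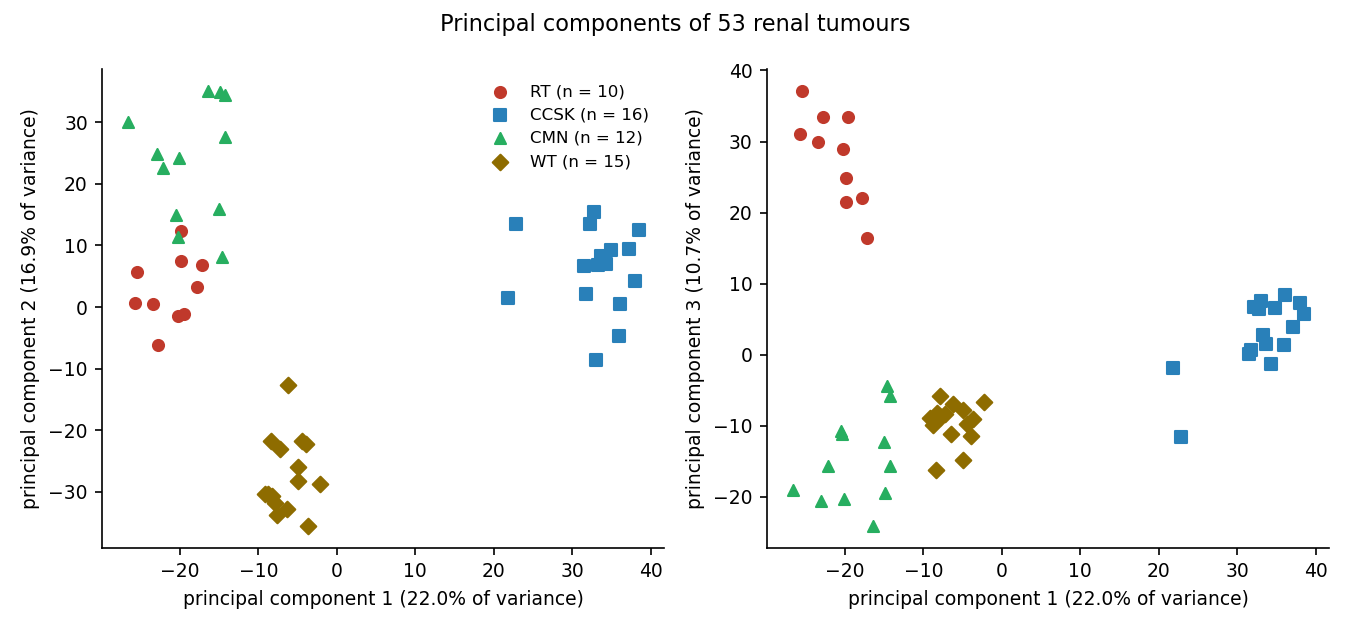
Principal components of 53 renal tumours, computed from all tested probesets; each point is 1 tumour, marked by type, and the axes are component scores with their percent of the variance. Component 1 (22.0%) separates CCSK, component 2 (16.9%) separates CMN from WT, and component 3 (10.7%) places the 10 RT above the other 43 tumours.

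*SMARCB1*, examined first because its loss defines the tumour, was lower in RT than in each of the other types. The mean log2 value was 9.34 ± 0.11 (SD, n = 10) in RT, 10.18 ± 0.17 (n = 16) in CCSK, 10.24 ± 0.27 (n = 12) in CMN and 10.63 ± 0.27 (n = 15) in WT. All 10 RT lay between 9.13 and 9.51, below the lowest non-RT tumour at 9.81. The difference from non-RT was 2.02-fold lower (log2 change -1.01 ± 0.10 SE, adjusted p = 1.92e-11). Against single types it was 1.79-fold lower than CCSK (adjusted p = 1.63e-11), 1.87-fold lower than CMN (3.38e-07) and 2.45-fold lower than WT (4.13e-11).

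**Figure D2:**
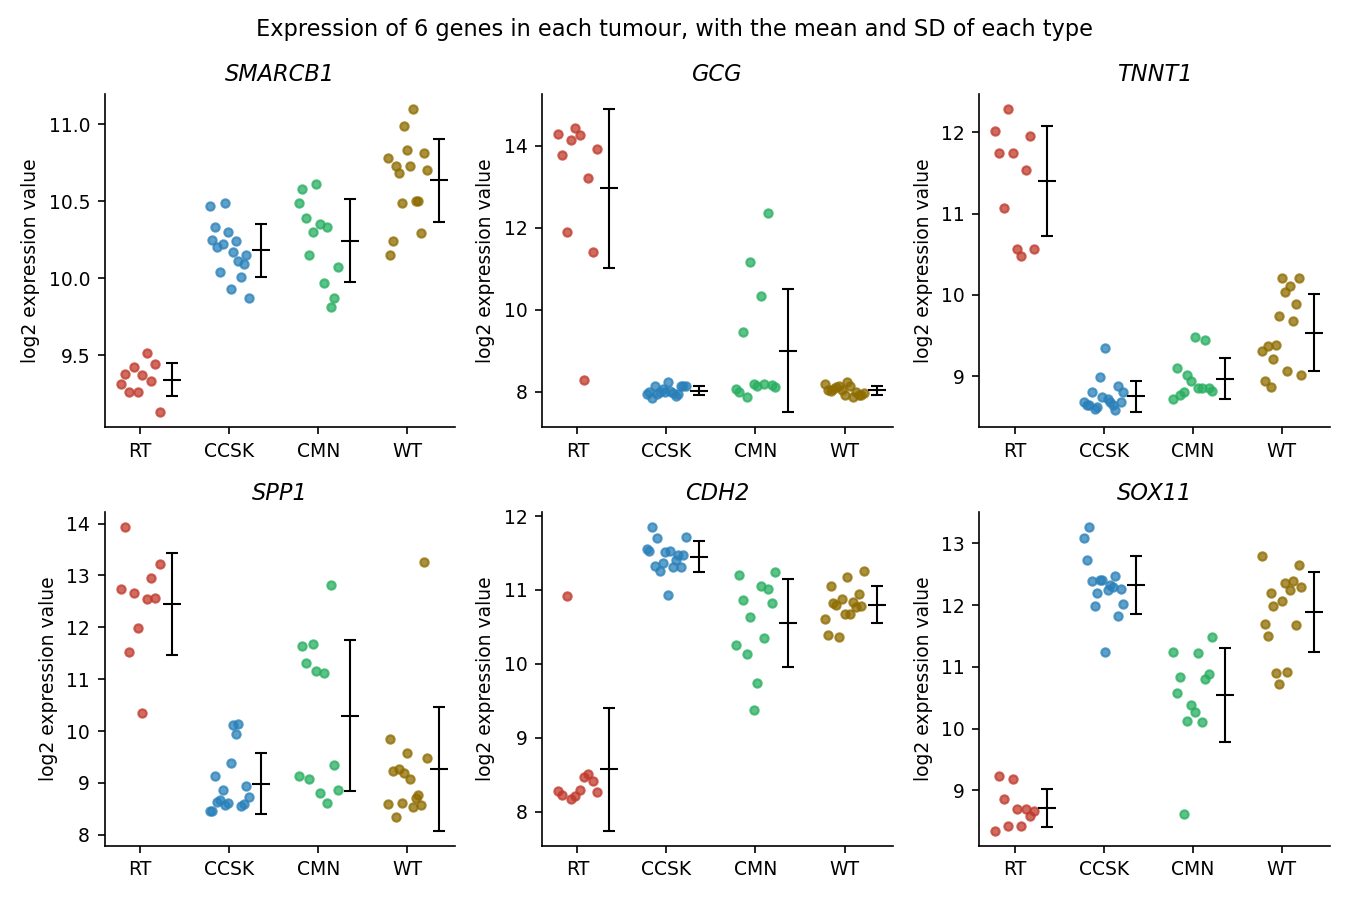
Log2 expression value (vertical axes, scaled separately per gene) of *SMARCB1*, *GCG*, *TNNT1*, *SPP1*, *CDH2* and *SOX11* by tumour type; each point is 1 tumour, and the bar beside each type is the mean with the SD over 10 RT, 16 CCSK, 12 CMN or 15 WT. The 10 RT lie below the other tumours for *SMARCB1* and above them for *TNNT1*, while 1 RT lies at 8.28 for *GCG* and 1 at 10.92 for *CDH2*, far from the rest of the group.

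The comparison of RT with the 43 non-RT tumours asks which genes and pathways are expressed differently in rhabdoid tumours. The largest increase among named genes was in *GCG*, which encodes the precursor of glucagon. Its mean was 12.95 ± 1.94 (SD, n = 10) in RT against 8.03 ± 0.11 in CCSK, 9.01 ± 1.49 in CMN and 8.04 ± 0.11 in WT, a log2 difference from non-RT of 4.65 ± 0.39 (SE, adjusted p = 2.21e-13), and 7 of the 10 RT lay above every non-RT tumour. *SPP1*, which encodes the secreted matrix protein osteopontin, was 7.95-fold higher (2.99 ± 0.40, adjusted p = 8.03e-08), but only 1 of the 10 RT lay above the highest non-RT tumour, a WT at 13.26. *COL5A2*, a chain of fibrillar type V collagen, was 5.73-fold higher (2.52 ± 0.40, adjusted p = 3.01e-06), with 8 of 10 RT above every non-RT tumour. *TNNT1*, the slow skeletal muscle troponin T, was 4.96-fold higher (2.31 ± 0.18, adjusted p = 8.42e-15), and 10 of 10 RT lay above every non-RT tumour. The same complete separation was seen for *RSU1*, a focal adhesion protein gene (4.64-fold, adjusted p = 1.69e-14), and for *NQO1*, the quinone reductase induced by oxidative stress (4.33-fold, adjusted p = 2.45e-20).

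Among 50 probesets of genes named by size of change and *SMARCB1*, 23 had a mean in some type under 8.86, the level of the dimmest 30% of probesets, and there a fold or its rank depends on the background. *GCG* in CCSK and WT, *MMP12* in all 3 other types and *SOX11*, *COL2A1*, *KIAA0644*, *CDH2* and *DACH1* in RT were among these. The remaining genes with the largest increases were *MYOF*, which encodes the membrane repair protein myoferlin (4.37-fold), the clone-named *FLJ22662* (3.84-fold), *MMP12*, the macrophage metalloelastase (3.64-fold), and *SERPINF1*, which encodes pigment epithelium-derived factor (3.57-fold, log2 change 1.83 ± 0.37 SE, adjusted p = 0.000178). *SERPINF1* did not pass against CMN alone (log2 change 0.29, adjusted p = 0.465). *FLJ22662* and *SERPINF1* had no RT above the highest non-RT tumour, whereas 8 of 10 RT were above it for *MYOF* and *MMP12*.

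Among lower genes, the largest change was in *SOX11*, a transcription factor of embryonic progenitors, which was 7.80-fold lower in RT (log2 change -2.96 ± 0.30 SE, adjusted p = 5.81e-11). Its mean was 8.71 ± 0.30 (SD, n = 10) in RT, 12.32 ± 0.47 in CCSK, 10.54 ± 0.76 in CMN and 11.89 ± 0.65 in WT. *ATP1B1*, the beta subunit of the sodium-potassium pump, was 7.31-fold lower (adjusted p = 6.39e-07), and *KIAA0644* was 6.23-fold lower (adjusted p = 2.21e-13), each with 10 of 10 RT below every non-RT tumour. *COL2A1*, which encodes the cartilage collagen, was 6.61-fold lower (-2.72 ± 0.53, adjusted p = 0.000101), although its CMN mean of 8.77 ± 0.51 (n = 12) was near that of RT, 8.55 ± 0.37. The adhesion genes *CDH2*, which encodes N-cadherin, and *CADM1* were 5.28-fold and 5.18-fold lower. *DACH1*, a transcription factor of the developing kidney, lay at 8.35 ± 0.05 (SD, n = 10) in RT and was 4.96-fold lower (adjusted p = 1.70e-06). *KCTD12* (5.40-fold lower), the growth factor gene *PTN* (4.62-fold) and the oncofetal antigen gene *TPBG* (4.61-fold) completed the set, with adjusted p-values of 0.000131, 1.74e-05 and 2.08e-05. Against single types, *COL2A1* (log2 change -0.22, adjusted p = 0.428), *CADM1* (-1.45, 0.0266) and *DACH1* (-0.88, 0.0115) did not pass against CMN, nor *KCTD12* (-0.71, 0.0302) and *TPBG* (-0.76, 0.0133) against WT.

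Gene lists fixed before the data were examined were then counted over genes with a name, each by its probeset with the highest mean, the counted probeset. Folds given for single members are those of the called probeset with the largest change, which can exceed the fold of the counted probeset. Names were at hand only for probesets that the authors had selected on these same tumours, so the counts and list tests are not independent evidence of a list's direction. Of all 2201 named genes, 856 had a probeset called higher and 675 one called lower in RT against non-RT, and the counts of a list should be read beside these. Of 111 list member probesets that passed against non-RT, 14 did not pass against CCSK alone, 50 against CMN and 18 against WT, in fits of fewer tumours. Of 168 such probesets 51 had a type mean among the dimmest 30%, 46 of them in RT, and their folds depend on the background. In RT these included *SALL1*, *EGFR*, *KIT*, *NTRK2*, *SMAD7*, *LEF1*, *NCAM1*, *GRB10*, *MYCN* and *GLI2*. The list of MYC and nucleolar target genes, which drive ribosome production and growth, was higher in RT. Of 16 named members 14 were higher, 1 was lower and 1 did not pass, and adjusted over the list alone 15 were higher and 1 lower. The list's median log2 change was 0.68 (camera adjusted p = 0.00262, and adjusted p = 0.307 with an estimated correlation). *TFRC*, the transferrin receptor gene, was 3.25-fold higher (1.70 ± 0.19 SE, adjusted p = 1.17e-09), *MYC* itself 2.60-fold higher (1.38 ± 0.21, adjusted p = 9.49e-07) and *HSPD1*, a mitochondrial chaperone gene, 1.83-fold higher (adjusted p = 0.00124, and 1.46-fold by its counted probeset). *MYCN* was the lower member (2.08-fold, adjusted p = 0.00734), and its call was lost when any 1 of the 10 RT was left out (highest adjusted p = 0.0148, without RT 15).

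Among 11 named members of the hypoxia and glycolysis list, again drawn from the authors' selection, 7 were higher and 4 did not pass; adjusted over the list alone 8 were higher and 2 lower. *SLC2A3*, a glucose transporter gene, was 2.89-fold higher (1.53 ± 0.22 SE, adjusted p = 5.63e-07), *BNIP3*, a mitophagy receptor gene, 2.64-fold higher (adjusted p = 6.51e-06), and *ENO1*, a glycolytic enzyme gene, 2.11-fold higher (adjusted p = 0.00148). The list test did not pass (adjusted p = 0.0607), but did without RT 10 (0.0479) and without the dimmest 30% of probesets (0.0396), within a range of 0.0396 to 0.0809 over the alternatives with the preset correlation, and its adjusted p was 0.357 with an estimated correlation. Of 6 named oxidative phosphorylation genes 3 were higher and 3 did not pass, with 5 higher adjusted over the list alone. *SDHB*, a subunit of respiratory complex II, was 1.40-fold higher (adjusted p = 3.64e-05), and the list test gave an adjusted p of 0.0876.

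Lists of developmental signalling were lower in RT, with the same limit on which genes had names. In the WNT pathway 5 of 11 named members were lower, 6 did not pass and 9 were lower adjusted over the list alone (median log2 change -0.54, camera adjusted p = 0.0219, and adjusted p = 0.250 with an estimated correlation). *LEF1*, a transcription factor gene of the pathway, was 4.13-fold lower (-2.05 ± 0.29 SE, adjusted p = 2.68e-07) and *TCF7L1* 1.99-fold lower (adjusted p = 9.59e-10). In the Notch pathway 4 of 6 were lower, 5 adjusted over the list alone (adjusted p = 0.0332, 0.0571 in a fit of all 4 types, and 0.307 with an estimated correlation); the receptor gene *NOTCH2* was 2.44-fold lower and the target gene *HES1* 2.04-fold lower. In the BMP and TGF-beta pathway 7 of 8 were lower, 8 adjusted over the list alone (adjusted p = 0.0219, and adjusted p = 0.253 with an estimated correlation), including the signal transducer *SMAD3* and the inhibitor *SMAD7*, both 1.81-fold lower.

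Receptor tyrosine kinases, the growth factor receptors, were lower for 8 of 13 named members and 5 did not pass. Adjusted over the list alone 8 were lower and 1 was higher (camera adjusted p = 0.0332, and adjusted p = 0.288 with an estimated correlation). *EGFR* was 4.09-fold lower (-2.03 ± 0.38 SE, adjusted p = 5.39e-05), *NTRK2* 2.94-fold (adjusted p = 0.00153), *IGF1R* 2.56-fold (0.000172) and *KIT* 2.30-fold (0.00410). *EGFR* did not pass against WT alone (log2 change -0.58, adjusted p = 0.0113), *IGF1R* (-0.23, 0.483) and *KIT* (-0.16, 0.102) against CMN, and *NTRK2* against CCSK (-1.36, 0.0172) or CMN (-1.09, 0.0402). In the IGF axis and imprinted genes 3 of 4 were lower, also 3 adjusted over the list alone, among them *IGFBP2* (2.60-fold, adjusted p = 2.06e-05) and *GRB10* (2.35-fold, 0.000117), and the list test gave an adjusted p of 0.112. *GLI2*, the one named Hedgehog gene, was 1.61-fold lower (adjusted p = 0.00113). These genes too had names only because the authors had selected them.

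Of 8 named HOX genes, which specify position along the body axis, 7 were lower and 8 adjusted over the list alone (median log2 change -0.98, camera adjusted p = 0.0219, and adjusted p = 0.357 with an estimated correlation). *HOXA10* was 3.30-fold lower (-1.72 ± 0.25 SE, adjusted p = 3.03e-07, and 2.76-fold by its counted probeset) and *HOXA11* 2.98-fold lower (adjusted p = 1.88e-06). Of 10 named nephron progenitor genes 5 were lower and 9 adjusted over the list alone (median -0.96, adjusted p = 0.0332, and adjusted p = 0.334 with an estimated correlation). The progenitor regulators *CITED1* and *SIX2* were 3.38-fold (adjusted p = 1.46e-05) and 3.07-fold (0.00190) lower, and *SALL1* had a log2 change of -1.62 ± 0.37 (0.000970). Against CMN alone *CITED1* (-0.33, adjusted p = 0.0370) and *SALL1* (-0.03, 0.603) did not pass, and *SIX2* did not against CCSK (-0.56, 0.0506). None of the 3 named genes of differentiated renal epithelium passed over all probesets, though 3 were lower adjusted over the list alone (list adjusted p = 0.284), and 2 of 4 podocyte genes were lower in both adjustments, among them *DACH1* (list adjusted p = 0.144). Of 5 neural crest genes 3 were lower in both adjustments, led by *FOXD1* (2.19-fold, adjusted p = 0.00159; list adjusted p = 0.162). All of these counts share the limit that only genes selected by the authors were named.

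Basement membrane genes were lower in RT for 6 of 9 named members, 1 was higher and 2 did not pass, and adjusted over the list alone 7 were lower and 1 higher. The list's median log2 change was -1.22 (camera adjusted p = 0.0349, 0.0571 in a fit of all 4 types, and 0.334 with an estimated correlation). *COL4A2*, a type IV collagen chain, was 4.44-fold lower (-2.15 ± 0.25 SE, adjusted p = 1.77e-09), and the laminin chains *LAMB1* and *LAMA4* were 3.70-fold (adjusted p = 7.06e-10) and 3.17-fold (1.47e-08) lower. *LAMB2*, another laminin chain, was 1.85-fold higher (adjusted p = 2.15e-11). Of 4 named endothelial markers, *CLDN5* (1.53-fold, adjusted p = 0.00336) and *PROX1* (1.17-fold, 0.00236) were lower, and 3 were lower adjusted over the list alone. The median log2 change of the 4 was -0.51 (list adjusted p = 0.203). Against CCSK, CMN and WT in turn, the list medians were -1.47, -1.34 and -0.55 for basement membrane genes. They were -0.32, -0.31 and -0.33 for the endothelial markers. Lower were 7, 6 and 4 of 9 basement membrane genes, and 2, 0 and 3 of 4 endothelial markers. Against CMN, *EMCN* (log2 change -1.02, adjusted p = 0.0386) and *PLVAP* (-0.46, 0.0335) did not pass. For both lists only genes selected by the authors could be counted.

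Fibrillar matrix genes went both ways, with *COL5A2* higher, *MMP2* 2.28-fold lower (adjusted p = 0.000989) and 4 of 6 not passing; adjusted over the list alone 2 were higher and 3 lower (list adjusted p = 0.619). The smooth muscle genes *TPM2* and *MYL9* were 3.33-fold (adjusted p = 0.000249) and 3.04-fold (4.82e-07) higher, both also adjusted over the list alone. Against CMN alone neither passed, with log2 changes of 0.08 for *TPM2* (adjusted p = 0.809) and 0.97 for *MYL9* (0.0213), 1 of 2 higher adjusted over the list alone. *TNNT1* was the one named skeletal muscle gene. Of 11 named neuronal genes 2 were higher, 5 lower and 4 did not pass, with 2 higher and 6 lower adjusted over the list alone (list adjusted p = 0.284). *NEFH* and *ENO2* were 2.98-fold (adjusted p = 9.81e-13, and 2.24-fold by its counted probeset) and 2.60-fold (1.10e-09) higher, while the neural adhesion gene *NCAM1* was 3.12-fold lower (9.05e-08). The authors' selection set which members of these lists had names.

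Chromatin regulators other than *SMARCB1* changed little or in both directions. Of 8 named SWI/SNF subunits, *SMARCB1* included, 2 were lower, *SMARCB1* and *SMARCD1*, and 1 higher, and adjusted over the list alone 6 were lower and 1 higher (list adjusted p = 0.144). *ARID1A* was 1.83-fold higher (adjusted p = 1.39e-05), and 1.59-fold by its counted probeset. *SMARCD1* was 1.27-fold lower (adjusted p = 0.00940), a call lost without RT 1, 5, 7, 8, 9, 12, 14 or 15 (0.0123 to 0.0294) and without CCSK 9 (0.0104). *SMARCA4*, the ATPase subunit, had a log2 change of -0.35 ± 0.11 SE that did not pass (adjusted p = 0.0166). Of 9 Polycomb subunits, which repress developmental genes, 3 were higher and 5 lower, with 3 and 6 adjusted over the list alone (list adjusted p = 0.469). *CBX6* was 2.36-fold higher (adjusted p = 3.89e-16) and *JARID2* and *BMI1* were 1.91-fold (1.94e-05) and 1.74-fold (0.000177) lower. By their counted probesets *CBX6* was 1.47-fold higher and *JARID2* 1.47-fold lower. *HDAC6*, the one named histone deacetylase gene, did not pass (adjusted p = 0.0188). These counts hold only genes the authors had selected.

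The remaining lists held few named genes, each selected by the authors. *CDKN1C*, which encodes a cyclin-dependent kinase inhibitor, was 2.06-fold lower (adjusted p = 0.00302) and was the 1 of 3 named G1 regulators that passed, with 2 lower adjusted over the list alone (list adjusted p = 0.283). *RRM2*, the one named DNA replication gene, was 1.63-fold higher (adjusted p = 0.00395, and 0.0152 without RT 3 or 0.0117 without RT 12). The p53 target genes *DDB2* and *CCNG1* were both 1.48-fold higher (adjusted p = 6.64e-05 and 0.000233). Against WT alone *CDKN1C* (log2 change -0.31, adjusted p = 0.218) and *RRM2* (0.31, 0.193) did not pass. Nor did *RRM2* (0.64, 0.0151), *DDB2* (0.30, 0.119) and *CCNG1* (0.47, 0.0146) against CMN. Of 4 immediate early and stress genes *HSPA1A* was 2.07-fold higher (adjusted p = 0.00724, and 0.0109 to 0.0194 without RT 3, 5, 7, 8, 9, 12 or 14) and *JUN* 1.75-fold lower (0.00106), with 2 higher and 1 lower adjusted over the list alone (list adjusted p = 0.601). Of 2 ribosomal protein genes 1 was higher, *RPS2* (1.28-fold, adjusted p = 0.000655), and 2 adjusted over the list alone. *RPS6* was counted by a probeset that did not pass (adjusted p = 0.0211) and had another that did (0.00361), which lost its call after quantile normalization (0.0553). The myeloid marker *ITGAM* was 1.12-fold lower (adjusted p = 0.00595, and 0.0121 to 0.0224 without RT 1, 3, 5, 7 or 15), and the B cell marker *BLK* did not pass (0.0128). Of 2 named simple epithelium genes 1 was lower, a gene whose probesets may match another copy and which is not reported by name, and *CLDN4* did not pass (adjusted p = 0.114). Lists of the mitotic cycle, pluripotency, T and NK cells, antigen presentation, interferon response, erythroid cells and cancer-testis antigens held 0 named genes and were not analysed here.

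**Figure D3:**
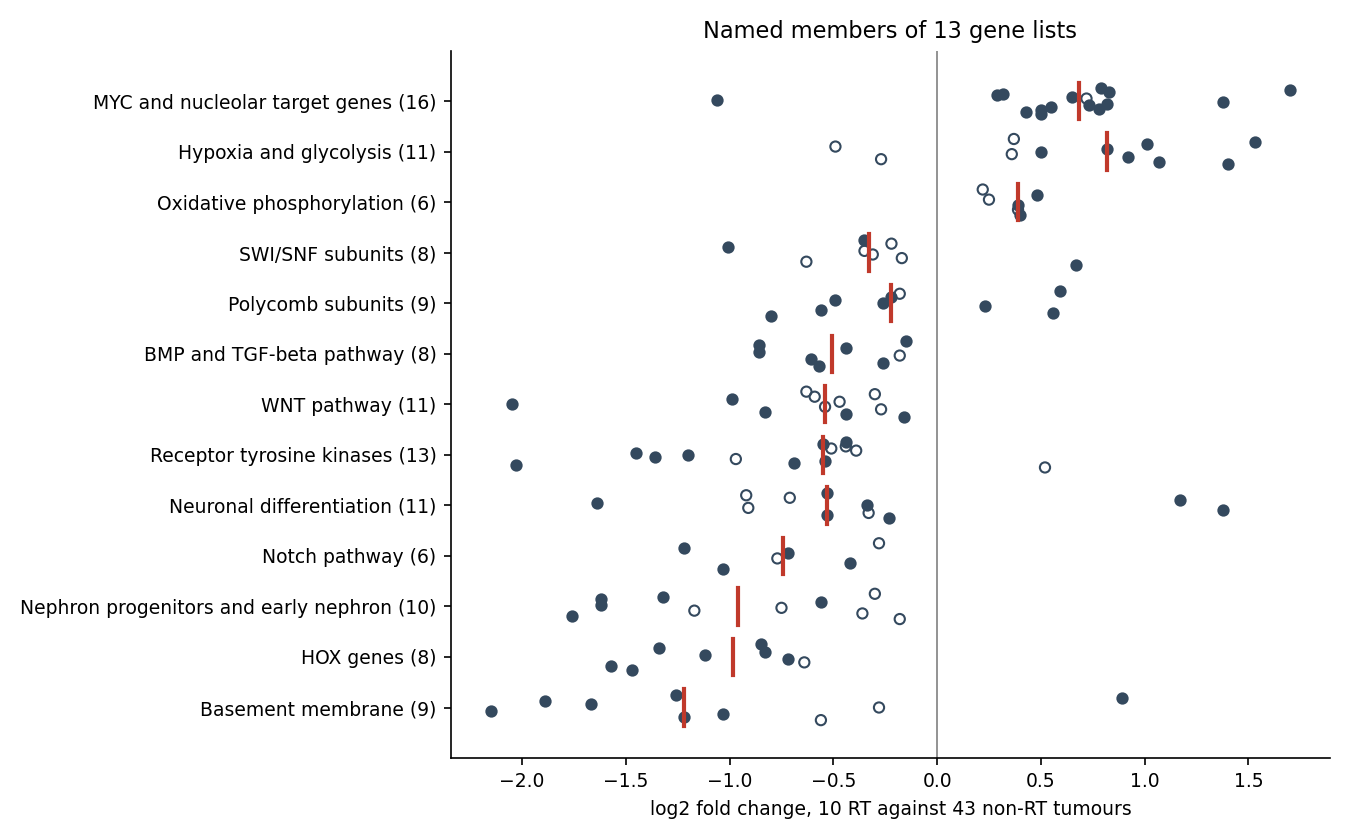
Log2 fold change of RT (10 tumours) against non-RT (43 tumours) for the named members of 13 gene lists, with the number of members in parentheses; each point is the probeset of a gene with the highest mean, filled where the adjusted p is under 0.01 and open otherwise, and the red line is the list's median. MYC and nucleolar target genes have a median of 0.68, and HOX and basement membrane genes have medians of -0.98 and -1.22.

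Over all 22280 tested probesets, 1874 were higher and 1043 lower in RT than in non-RT at an adjusted p under 0.01, and 119 and 197 of these differed at least 2-fold. The share of higher calls, 64.2%, depended on the test: a t-test with unequal variances called 1362 higher and 1818 lower (42.8% higher). Common to both with the same sign were 2075 calls, 1148 higher and 927 lower. Calls by limma alone mostly had a larger SD in RT than in non-RT, in 90.8% of 726 higher and 77.6% of 116 lower ones. Of the 214 higher and 891 lower calls made with unequal variances alone, 0% did. Calls on which the tests differ are selected for unequal spread, so these shares follow largely from the tests themselves. A fit of all 4 types called 2418 higher and 1989 lower (54.9% higher). Drawing 10 non-RT tumours at random gave a median of 59.7% higher over 100 draws.

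RT and CCSK, another aggressive mesenchymal renal tumour, differed at 5079 probesets, 2858 higher and 2221 lower in RT. *GCG* (log2 change 4.92 ± 0.46 SE), *SPP1* (3.46 ± 0.29), *TNNT1* (6.25-fold, adjusted p = 1.09e-12), the tropomyosin gene *TPM2* (6.21-fold, 8.11e-15) and *RSU1* (5.91-fold, 1.11e-10) had the largest measured increases among named genes, with *GCG* in CCSK at 8.03, below nearly all probesets. The largest decrease was in *PCP4*, a calmodulin regulator, with a log2 change of -4.41 ± 0.40 (SE, adjusted p = 1.20e-09). Its mean was 8.45 ± 0.09 (SD, n = 10) in RT, among the dimmest 30% of probesets, and 12.86 ± 1.33 (n = 16) in CCSK. *COL2A1* (15.7-fold), *ATP1B1* (15.6-fold), *KCTD12* (15.0-fold) and *SOX11* (12.2-fold) were also lower, with adjusted p-values from 5.30e-16 to 4.84e-14.

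Of the 21 lists tested, 11 were called in RT against CCSK, over genes named through the authors' selection. MYC and nucleolar targets were higher, with 14 of 16 members higher and 1 lower, and 15 and 1 adjusted over the list alone (adjusted p = 0.00193, and adjusted p = 0.144 with an estimated correlation). All 8 HOX genes were lower, as were 8 adjusted over the list alone (median log2 change -1.50, adjusted p = 0.00193, and 0.144 with an estimated correlation), and all 6 Notch genes were lower, also 6 adjusted over the list alone (adjusted p = 0.0200, and 0.144). Receptor tyrosine kinases were lower for 9 of 13 and higher for 1, with 10 and 1 adjusted over the list alone (adjusted p = 0.00725, and 0.104), including *EGFR* (7.18-fold, adjusted p = 1.95e-15) and *KIT* (5.37-fold, 1.68e-16). WNT genes were lower for 7 of 11 in both adjustments (adjusted p = 0.00770, and 0.104), BMP and TGF-beta genes for 7 of 8 in both (0.0185, and 0.104), and IGF axis and imprinted genes for 4 of 4 in both (0.0155, and 0.144). Nephron progenitor genes were lower for 5 of 10 in both (0.0239, and 0.144) and basement membrane genes for 7 of 9, with 1 higher, in both (0.0368, and 0.181). Of 4 named endothelial markers 2 were lower than in CCSK, *CLDN5* (log2 change -1.08, adjusted p = 1.71e-09) and *PROX1* (-0.34, 8.70e-06), and 3 adjusted over the list alone (median -0.32, list adjusted p = 0.136). In each pair of list values the latter is the adjusted p with an estimated correlation.

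Hypoxia and glycolysis genes were higher than in CCSK for 8 of 11 and lower for 2 in both adjustments, and neural crest genes were lower for 4 of 5 in both. Both list calls were marginal (adjusted p = 0.0485 for each, and adjusted p = 0.261 and 0.168 with an estimated correlation). The hypoxia call was lost without RT 1 (0.0526), RT 12 (0.0509), RT 14 (0.0558), RT 15 (0.0507) or CCSK 9 (0.0505), and the neural crest call without any 1 of RT 1, 5, 7, 9, 10, 12, 14 or 15 (up to 0.0534). Over all alternatives with the preset correlation the adjusted p ranged from 0.0305 to 0.0765 for hypoxia and glycolysis and from 0.0437 to 0.0583 for neural crest.

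CMN, a spindle cell tumour of infancy, gave the fewest calls against RT, with 1461 probesets higher and 1075 lower in RT. It also had the fewest tumours (n = 12), and a number of calls depends on the number and spread of the tumours as well as on the differences. *GCG* was 15.4-fold higher (log2 change 3.95 ± 0.69 SE, adjusted p = 0.000298), although CMN tumours reached up to 12.36. *TNNT1* was 5.38-fold higher (2.43 ± 0.20, adjusted p = 3.05e-08), *SPP1* 4.43-fold (2.15 ± 0.51, adjusted p = 0.00448, and 0.0101 without RT 3), *TFRC* 4.10-fold (adjusted p = 2.53e-08) and *NQO1* 3.80-fold (2.67e-07). *KIAA0644* was 10.4-fold lower (-3.38 ± 0.14, adjusted p = 2.80e-13), *PTN* 9.73-fold lower (2.91e-06) and *ATP1B1* 9.70-fold lower (2.43e-07). The matrix gene *MXRA5* and the protease inhibitor gene *SERPINE2* were 8.32-fold (adjusted p = 1.15e-06) and 7.46-fold (1.02e-06) lower.

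Against CMN 3 lists were called, again over the authors' selection. MYC and nucleolar targets were higher for 11 of 16 in both adjustments, 5 not passing (adjusted p = 0.000933, and adjusted p = 0.270 with an estimated correlation). Receptor tyrosine kinases were lower for 6 of 13 in both (adjusted p = 0.0146, and 0.0694 with an estimated correlation), led by *EGFR* (6.82-fold, adjusted p = 5.93e-08). Basement membrane genes were lower for 6 of 9 and higher for 1 in both (adjusted p = 0.0146, and 0.270 with an estimated correlation), led by *COL4A2* (6.13-fold, adjusted p = 1.23e-08). HOX genes had a median log2 change of -0.08 with 2 of 8 lower in both adjustments, and the list was not called (adjusted p = 0.364). Nor were nephron progenitors, lower for 2 of 10 in both adjustments (median -0.16, adjusted p = 0.188), WNT genes, lower for 4 of 11, and 5 adjusted over the list alone (0.109), Notch genes, lower for 3 of 6, and 4 adjusted over the list alone (0.130), or BMP and TGF-beta genes, lower for 3 of 8, and 5 adjusted over the list alone (0.0730). Hypoxia and glycolysis genes were higher for 3 of 11, and 4 adjusted over the list alone, and lower for 2 in both (list adjusted p = 0.188). *BNIP3* passed (log2 change 1.26, adjusted p = 0.000949) and *SLC2A3* did not (0.83, 0.056). *ENO1* passed by its counted probeset (0.70, 0.00873) but not by the named one (0.65, 0.171). The 4 named endothelial markers had a median log2 change of -0.31 against CMN (list adjusted p = 0.215).

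RT and WT differed at 4510 probesets, 2175 higher and 2335 lower in RT. *GCG* had a log2 change of 4.91 ± 0.47 (SE, adjusted p = 1.61e-08), with a WT mean of 8.04, among the dimmest 30% of probesets. *COL5A2* was 14.3-fold higher (log2 change 3.84 ± 0.20 SE, adjusted p = 4.36e-13), with means of 12.82 ± 0.62 (SD, n = 10) in RT and 8.98 ± 0.44 (n = 15) in WT. *SPP1* was 9.01-fold higher (adjusted p = 3.06e-06), the fibrillar collagen gene *COL3A1* 7.70-fold (9.96e-06) and *SERPINF1* 6.20-fold (1.88e-11). *COL2A1* was 10.5-fold lower (-3.40 ± 0.19, adjusted p = 8.41e-13), *LYPD1* 10.0-fold, the adhesion receptor gene *ADGRG2* 9.88-fold, *DACH1* 9.50-fold (2.61e-19) and *SOX11* 9.06-fold (2.56e-11).

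Against WT 7 lists were called over genes the authors had selected, the lower ones led by the nephron progenitors, the lineage that WT resembles. Of 10 named progenitor genes 7 were lower and 8 adjusted over the list alone (median log2 change -2.01, adjusted p = 0.00271, and adjusted p = 0.246 with an estimated correlation). *SIX2* was 8.31-fold lower (-3.05 ± 0.20, adjusted p = 1.88e-11) and *SALL1* had a log2 change of -2.90 ± 0.15 (4.52e-13), with its RT mean of 7.72 among the dimmest 30% of probesets. All 8 HOX genes were lower in both adjustments (adjusted p = 0.00358, and 0.268 with an estimated correlation), with *HOXA10* 5.44-fold lower (log2 change -1.95 by its counted probeset). SWI/SNF subunits, *SMARCB1* included, were lower for 6 of 8 and higher for 1 in both (adjusted p = 0.0360, and 0.270), WNT genes lower for 8 of 11 in both (0.0254, and 0.246), and BMP and TGF-beta genes lower for 7 of 8, and 8 adjusted over the list alone (0.0357, and 0.268). MYC and nucleolar targets were higher for 11 of 16 and lower for 1, with 13 and 1 adjusted over the list alone (0.00515, and 0.270), and hypoxia and glycolysis genes were higher for 7 of 11, and 8 adjusted over the list alone (0.0357, and 0.380). In each pair the latter value is the adjusted p with an estimated correlation. *MYC* was 3.75-fold higher and *MYCN* 4.30-fold lower than in WT. Fibrillar matrix genes went both ways, 2 of 6 higher, 2 lower and 2 not passing, in both adjustments (median log2 change -0.21, while the test leaned upward, adjusted p = 0.778), and basement membrane genes were lower for 4 of 9 and higher for 1 in both (list adjusted p = 0.219). Endothelial markers were lower than in WT for 3 of 4 in both (median -0.33, list adjusted p = 0.326).

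The intersection of the 4 comparisons asks which genes set RT apart from each other type and not only from their average. At an unadjusted limma p under 0.001 in all 4 comparisons with the same direction, 419 probesets were higher and 241 lower in RT, naming 311 and 173 genes. Ranked by their smallest change over the 3 types, *GCG* (15.4-fold above CMN, the smallest of its 3 measured changes), *SPP1* (4.43-fold) and *NQO1* (3.80-fold) led the higher genes, with *TNNT1*, *RSU1*, *MMP12*, *MYOF*, *COL5A2*, *FLJ22662* and the aldehyde dehydrogenase gene *ALDH7A1* following. *ALDH7A1* was 3.32-fold higher than CCSK, 2.83-fold than CMN and 2.82-fold than WT. The lower genes were led by *KIAA0644*, *CDH2* and *SOX11*, whose smallest decreases were 4.94-fold, 3.95-fold and 3.56-fold, and included *PTN*, *LAMA4*, *LAMB1*, *LEF1*, *PLCB1* and *ATP1B1*. *IRS2*, which encodes an adaptor of insulin and IGF signalling, was 6.89-fold lower than CCSK, 2.84-fold than CMN and 2.62-fold than WT, and 10 of 10 RT lay below every non-RT tumour.

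The 4 comparisons share the RT arrays, which alone raises the overlap. Had the 3 single-type lists been unrelated, 13.6 higher and 8.40 lower probesets would have been shared by chance. Lists from independent tumours can share more, because true differences recur in them. In 100 splits of the tumours, the real one included, the others gave at most 7 in both directions together. The RT were also divided at random into parts of 4, 3 and 3 tumours, each compared with a different type. The median overlap over 100 draws was 102 higher (range 75 to 131) and 55 lower (33 to 70). Unrelated lists would have shared 2.25 and 0.745. Each draw kept the limit of p under 0.001 in RT against non-RT, which used all the RT. The smaller parts also lower the number of calls.

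**Figure D4:**
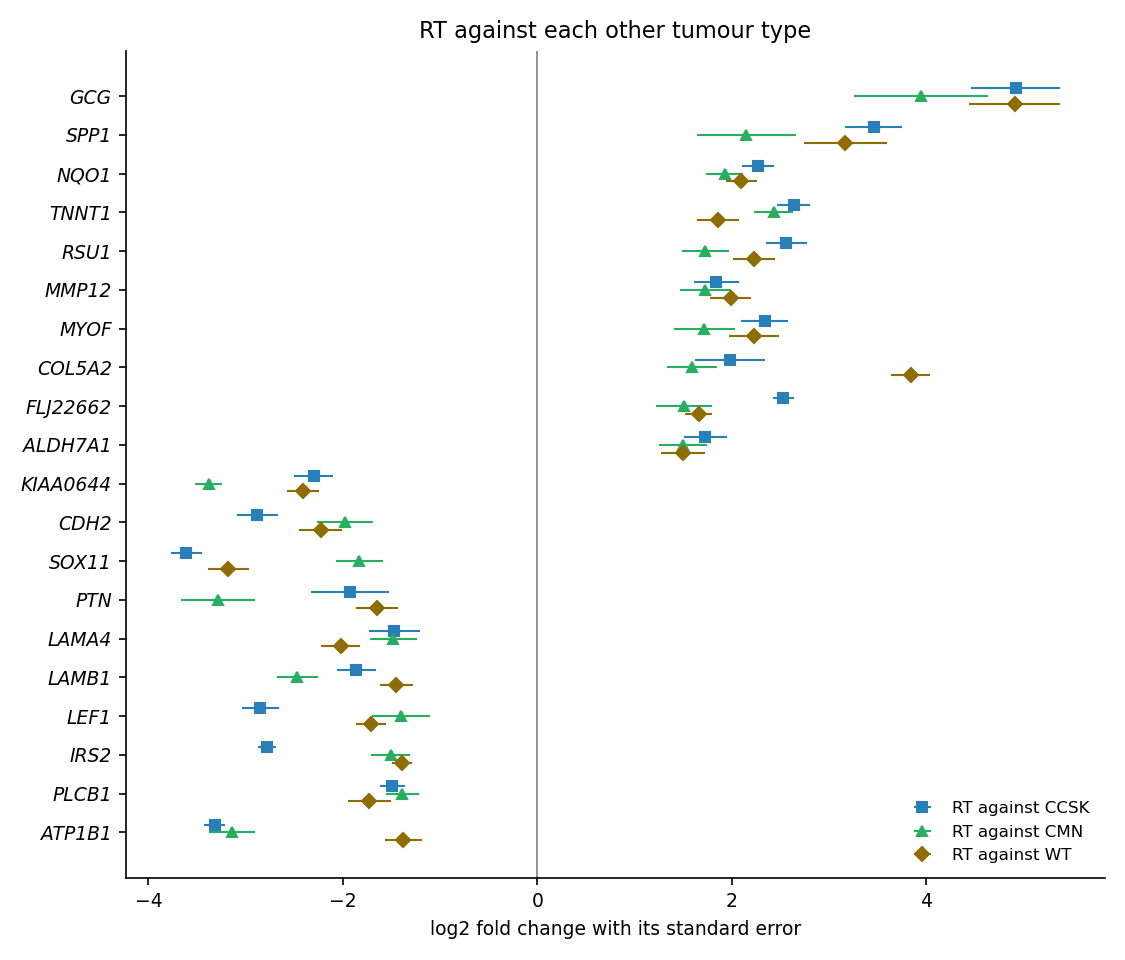
Log2 fold change of RT (10 tumours) against CCSK (16), CMN (12) and WT (15), with the standard error as a bar, for the 10 higher and 10 lower genes with the largest smallest change over the 3 types. *GCG* has the largest changes, 4.92, 3.95 and 4.91, and *COL5A2* differs more from WT (3.84) than from CCSK (1.98) or CMN (1.59).

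In the authors' deposited table of RT against non-RT, 1237 probesets had a fold above 1 and 1684 below it. Of the 2917 limma calls, 1956 were in the authors' deposited table and 961 were not. Of the 660 probesets different from each type, 409 were in the authors' deposited table of that intersection, which lists 426 probesets, 261 with a fold above 1 and 165 below it. In the authors' deposited table of over-represented processes, made from 766 genes, 138 genes of developmental processes were observed against 64.82 expected (p = 1.18e-15). Neurogenesis in the authors' deposited table had 63 genes against 17.68 (p = 2.84e-15), cell adhesion 46 against 18.74 (p = 1.44e-06), and receptor protein tyrosine kinase signalling 23 against 6.36 (p = 4.48e-05). The authors' deposited table takes its expected numbers from a reference list of human genes, not from the genes on the array.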

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

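The draws of 10 non-RT tumours and the tests of vessel content were chosen after the results had been seen. Among 114 probesets of named genes, 16 had 1 RT tumour far from the other 9 by Dixon's test, where chance gives about 1 in 20. *GCG* lay at 8.28 in RT 10, near the means of 8.03 in CCSK and 8.04 in WT, while the next lowest RT lay at 11.40. The same tumour had the lowest *SDHB*, 9.69, and the highest *MSX2*, 8.55, and its log2 3′ to 5′ difference, averaged over *GAPDH* and beta-actin, was 2.42 against 0.968 to 1.61 in the other 9 RT. RT 5 stood above the other RT at 10.92 for *CDH2* (next highest 8.51), 12.71 for *CADM1* (9.95) and 10.24 for *NTRK2* (9.16), which were lower in RT than in non-RT, and at 10.39 for *TNC* (9.45), which did not pass that comparison (adjusted p = 0.0606). RT 14 stood above the others at 10.41 for *TMEM100* (next highest 8.41), 9.51 for *CITED1*, 10.49 for *PTN* and 10.24 for *NID2*. RT 1 had the highest *LAMB1*, 10.80, and *SMAD3*, 9.85, RT 3 the highest *KIT*, 8.84, and *FOXD1*, 9.82, and RT 12 the highest *FMOD*, 10.27. No explanation was tested for these single tumours.

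More probesets were higher than lower in RT against non-RT (64.2% of calls), while the unequal-variance test gave 42.8% higher and a fit of all 4 types 54.9%. Array scaling and RNA quality were argued against as the whole cause, since the share was 65.0% after quantile normalization and 64.0% with the RNA quality covariate. Unequal spread with unequal group sizes could account for part of it: with 10 non-RT tumours drawn at random the median share was 59.7% (range 50.63 to 67.11), and 62.26% with unequal variances in the same draws. Of calls by limma alone, 90.8% of 726 higher and 77.6% of 116 lower ones had the larger SD in RT, but calls on which the tests differ are selected for unequal spread. Calls shared by both tests were 1148 higher and 927 lower. Unequal spread cannot be told apart from a true excess, because the drawn share lay between the values set for each outcome, and a difference between tumour types stays open, untested.

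The 6 basement membrane genes called lower in RT had a median log2 change of -1.46. RNA quality was argued against, since 6 of 6 remained called with the covariate (median -1.40). Fewer vessels in RT may contribute: the 4 named endothelial markers had a median of -0.51 (a permutation test of its difference from -1.46 was run and is void, because the 6 genes were chosen as lower), and with their mean as a covariate the median was -1.33 and 4 of 6 genes stayed called. *COL4A1* went from -1.03 ± 0.23 (SE) to -0.76 ± 0.29 (adjusted p = 0.0678) as its change shrank, and *NID2* from -1.26 ± 0.32 to -1.23 ± 0.41 (0.0340) as its error grew. This cannot be told apart from lower expression in the tumour cells, because only *CLDN5* (10.02 ± 0.13 SD in RT, 10.63 ± 0.50 in non-RT) and *PLVAP* (9.39 ± 0.19, 9.99 ± 0.62) lay above the dimmest 30% of probesets, and *EMCN* and *PROX1* did not.

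The tumours were reassigned to groups of the same sizes, in 100 splits with the real one included. For each count only 1 of 100, the real split, gave as many calls, which argues against a random grouping of the tumours. The splits cannot show whether a call reflects tumour type or something that goes along with it. The real number and the highest of the other splits were 2917 and 2 for RT against non-RT, 5079 and 1 against CCSK, 2536 and 0 against CMN, 4510 and 83 against WT, and 660 and 7 for the intersection. They were 5040 and 2 for CCSK against the rest, 3502 and 0 for CMN and 3886 and 766 for WT.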

How the results depend on the processing

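Leaving out CCSK 9, leaving out CMN 11, CMN 12 and CMN 13, and drawing 10 non-RT tumours were tests chosen after the results had been seen. The arrays CCSK 16 and CCSK 18, which also had large beta-actin differences, were not left out in a test of their own. Of 679 values of 33 counts, shares and list totals over the alternatives, 632 stayed close (within 1.5 times, for a count) and 47 moved. Of 3362 values for 153 results of named genes, 3246 kept direction and call, 116 lost the call and 0 reversed. The pseudocount alternative was not run because the values are not linear. Signal near background limits the changes that dim probesets can show.

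With unequal variances 1818 probesets were lower in RT against non-RT and 42.8% of calls were higher, 36.3% were higher in CMN against the rest, and WT against the rest had 2547 lower and 51.0% higher. The fit of all 4 types gave 1989 lower in RT against non-RT, 2597 lower in CMN, 2461 lower in WT and 639 higher in the intersection. Array weights gave 4082 lower in CCSK, 3108 higher and 2912 lower in CMN and 2452 lower in WT, each against the rest; the cause was not tested. A 2-fold limit left 119 higher and 197 lower in RT against non-RT, and 10 drawn non-RT tumours gave 754.5 and 509, as fewer tumours enter. Dividing the RT gave an intersection of 102 higher and 55 lower, again with fewer tumours.

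With an estimated correlation 0 lists were called higher or lower in RT against non-RT, CCSK, CMN or WT; the cause was not tested. Lists called higher in RT against non-RT were 2, not 1, without the dimmest 30% of probesets, and 1 to 2 when 1 RT tumour was left out (2 without RT 10). Lists called higher against CCSK were 1, not 2, with the mean of all probesets of a gene, the probeset of highest variance, quantile normalization, the RNA quality covariate, the fit of all 4 types or without CCSK 9, and 1 to 2 when 1 RT tumour was left out (1 without RT 1, 12, 14 or 15); the list lost was hypoxia and glycolysis, and the cause was not tested. Leaving out 1 RT tumour gave 1619 to 1849 higher and 838 to 997 lower probesets in RT against non-RT.

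The labels give each tumour a type and a number, and state no pairing between types. Over 62 same-numbered pairs across types the median correlation of deviations was 0.0390 (range -0.189 to 0.501), against -0.000315 for other pairs across types, and 21 were over 0.1. The numbers were not taken as pairing, since none is stated and the median was small. With the number as a block RT against CCSK had 1464 higher and 1392 lower, RT against CMN 916 higher, RT against WT 1166 higher and 1422 lower, CCSK against the rest 1717 lower, and the intersection 194 higher and 124 lower. The block ended 21 calls of named genes.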

Other observations

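The test of other chromosome arms was chosen after the result for 22q had been seen. The genes named here are those with the largest measured changes in each type, and no list was tested for these comparisons. *FOXF1*, a forkhead factor of mesenchyme, had a mean of 11.19 ± 0.26 (SD, n = 16) in CCSK against 8.29 in RT, 8.34 in CMN and 8.33 in WT, a log2 difference of 2.86 ± 0.05 (SE, adjusted p = 2.36e-46). The other types lay among the dimmest 30% of probesets for *FOXF1*, for *LHX2*, a LIM homeobox factor (log2 change 2.92 ± 0.08), and for *PCP4* (4.21 ± 0.22), so that these sizes depend on the background. The neurofilament gene *NEFL* was 10.8-fold (adjusted p = 3.85e-30) and the chaperone gene *HSPA2* 8.91-fold higher. The matrix gene *TNC* (3.38-fold, adjusted p = 9.97e-05), *TPM2* (3.37-fold) and *REXO2* (3.23-fold) were lower. Names come from the authors' selection for RT, so other genes of each type could not be named here; limma called 2456 probesets higher and 2584 lower in CCSK.

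In CMN the matrix gene *MXRA5* was 4.96-fold higher (adjusted p = 2.12e-09), *TNC* 4.56-fold (7.70e-06) and *FMOD*, which encodes the collagen-binding fibromodulin, 4.23-fold (3.59e-12), beside the homeobox gene *HLX1* (5.41-fold, 1.03e-18) and *PROM1* (4.08-fold, 6.89e-08). The cartilage collagen gene *COL2A1* (5.97-fold, adjusted p = 6.81e-05) and *HSPA2* (3.52-fold, 0.00101) were lower in CMN, and another decrease is not reported by name. In WT the nephron lineage regulator *PAX2* lay at 11.57 ± 0.49 (SD, n = 15), 6.78-fold above the rest (adjusted p = 1.84e-17), and *SIX2*, another such regulator, at 12.06 ± 0.43, 5.38-fold (3.85e-13), with *ADGRG2* 9.43-fold, *LYPD1* 7.74-fold and *WASF3* 5.80-fold higher. For *ADGRG2* the other types all lay among the dimmest 30% of probesets, as did RT and CMN for *PAX2*. *COL5A2* (5.66-fold, adjusted p = 5.24e-09), *COL3A1* (5.48-fold) and the mesenchymal filament gene *VIM* (4.18-fold, 4.21e-13) were lower in WT.

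*SMARCB1* lies on chromosome arm 22q, and a hypothesis was that loss of the arm in rhabdoid tumours lowers its other genes. Of 50 named genes on 22q without *SMARCB1*, 52% were lower in RT than in non-RT, against 55.4% on the other arms (odds ratio 0.871, 0.477 to 1.60, Fisher's exact 2-sided p = 0.667), with median log2 changes of -0.12 and -0.16. The value fell on the side set in advance for no loss, but within its spread, and the reading was changed to undecided after the value was seen, since the interval leaves room for a moderate effect. The 52% therefore neither shows nor excludes loss of 22q in these tumours.

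The same count over 39 arms gave shares of lower genes that differed from the other arms at 1p (36.1% of 122 genes, adjusted p = 0.000519), 19q (27.3% of 44, 0.00347), 1q (73.4% of 94, 0.00367), 3p (75.4% of 65, 0.00872), 18q (84.6% of 26, 0.0184) and 14q (38.8% of 67, 0.0391). Neighbouring genes are not independent, so these p-values are too small, and no explanation was tested.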
